A study of Drosophila melanogaster with 12 samples.

How the data were processed

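Polyadenylated RNA of Drosophila melanogaster was profiled in 12 libraries: whole larvae at 72, 96 and 120 h after egg laying, whole eye-antennal discs at the same ages and at the white prepupal stage (WPP), discs attached to the mouthparts at 72 h, and separated eye and antenna parts at 96 and 120 h. Per the labels' protocols, larvae of a white mutant strain grew on yeast-glucose medium and live larvae were dissected. RNA was taken up in Trizol and selected for poly(A) tails, primed with random hexamers, joined to adapters for ligation-mediated PCR, and size-selected on gels. Every group held 1 library, and groups were taken from the labels. The tissue named whole disc here includes the eye and antenna parts.

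The deposited values are 1 number per gene and library in a single table of 10893 FlyBase gene identifiers. TopHat and Cufflinks and the genome build dm3 are named per the submitters' processing notes, without versions, and the annotation, the strand setting and the rule by which genes entered the table are not given in the sources used here. No header names the unit. It was read as FPKM (fragments scaled to transcript length and to the mapped total), which the authors' use of Cufflinks per the submitters' processing notes and the values themselves point to: they are not whole and sum to between 939303 and 2210255 per library. A cluster number from 1 to 11 stands beside each gene in the deposited table, was made by the authors from these samples by a method not given in the sources used here, and was used only to describe where gene lists fall. Numbers of reads are unknown, so no counting interval is given. An exact 0 was taken as listed at 0 and never as a measured absence. Where strand is not used, reads of genes that overlap on opposite strands cannot be told apart, and whether it was used is unknown here, so values of overlapping genes are uncertain. So are single values of near-identical gene copies, such as those of the Lcp, Tweedle, Sgs, Jon and Eig71E families.

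The reference annotation BDGP6.54 was used only for gene symbols, the longest annotated transcript of each gene and the overlap of gene spans. A symbol was found for 10308 identifiers (94.6%), and 585 without one kept their identifier. No coordinates are given, because the build of the reference is not the one the authors used. Gene lists were written with the symbols in use when they were fixed, and 10 names were carried to newer symbols by a short table. Analyses were run in R 4.3.3 with limma 3.58.1 and in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6.

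Values were tested as log2(FPKM + 1), so that every fold is on that scale and understates the change of low genes. Since no group had a replicate, the tested comparisons took the deviation between matched pairs as error. In the first fit, lmFit and eBayes of limma (with trend and robust set) were run on the eye part, antenna part and whole disc at 96 and 120 h with terms for tissue and age, which gave the contrast of 120 h with 96 h and that of eye with antenna part. In the second, whole disc and whole larva at 72, 96 and 120 h were fitted with terms for tissue and age, which gave the contrast of disc with larva. Each fit had 6 libraries and 2 residual degrees of freedom, kept genes with at least 1 FPKM in at least 2 of its libraries, and used two-sided p adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The error term holds any true interaction of tissue and age as well as the spread between libraries. Nothing in the labels says how many animals were pooled for a library, and p-values measure the spread between these libraries alone, which may be technical.

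The 7 other comparisons set 1 library against 1 and used a rule of size: a difference of at least 1 in log2(FPKM + 1), or 2-fold, with at least 5 FPKM in the higher library. They have no replicate check. To describe the spread between separately made libraries, each whole disc was compared with the weighted mean of its eye and antenna parts, the weight being the value in steps of 0.01 with the lowest median absolute deviation over genes that differed at least 4-fold between the parts.

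For 25 lists of genes the number of members past each test or rule was counted, with the Benjamini-Hochberg adjustment repeated over the list alone. They were retinal determination, furrow signalling, photoreceptor and cone cell specification, E(spl) and Notch targets, phototransduction, neuron, glia, antenna and appendage patterning, ecdysone response, cell cycle, ribosome biogenesis, eye pigment, IRRE adhesion and pattern, fat body, salivary gland glue, muscle, larval and pupal cuticle, hemocyte, midgut and digestion, trachea, neuroblast and brain, male germ line, male dosage compensation, heat shock and stress, and mitochondrial genome. A list's median was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of the libraries compared. Named genes were the 10 highest rises and 10 deepest falls among genes past the test with the same direction in every pair (for single pairs, past the rule of size), leaving out genes with only a CG or CR number, up to 4 members of each list with the largest change, and any member of the retinal determination, furrow, photoreceptor and antenna lists. The lists, the rule for named genes, the fits and the first set of alternatives were fixed before the data were examined. Long-transcript genes beyond that rule, the list of 10 ring gland genes and the restriction to transcripts of at least 1000 nt were chosen after the values were seen.

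The alternatives were pseudocounts of 0.1 and 5, other filters on low values, scaling of libraries by the median ratio over expressed genes or to a common total (TPM), eBayes without trend and robust, fits without each pair, fits on the eye and antenna parts alone, the disc with mouthparts in place of the disc at 72 h, and for single pairs floors of 1 and 20 FPKM and a 4-fold rule. Added after the data were seen were transcripts of at least 1000 nt, fits without each single library, genes above 0 in both libraries, and the WPP pairs without the genes near 0 in that library alone.

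The procedures were tested on simulated data. With the spread of each gene as fitted, 100 genes changed by 1 and 100 by 2 on the log2 scale were recovered for 54% and 82% in the age contrast, with 15 false calls among 151 (9.93%). For eye against antenna the recovery was 30% and 78%, with 17 false calls among 125 (13.6%). For disc against larva it was 2% and 46%, with 14 false calls among 62 (22.6%). More of the simulated calls were thus false than the threshold states. With spreads drawn from the fitted prior the false calls were 3 of 102 (2.94%), 3 of 69 (4.35%) and 0 of 0 in the 3 contrasts, and the recovery was 21% and 78%, 2% and 64%, and 0% and 0%. Recovery and the share of false calls depend on how many genes change and by how much. With 5004 of 9993 genes called in the real contrast of disc with larva, these rates do not carry over to it. A simulated whole disc with an eye share of 40% gave 41% back, a library SD of 0.2 gave 0.185, a cell cycle list shifted by 1 came out at percentile 100, and 1 of 25 unshifted lists lay outside the central 95%.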

Results

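Messenger RNA of the eye-antennal imaginal disc of Drosophila melanogaster, the larval epithelium from which the adult eye, antenna and much of the head capsule form, was profiled by RNA sequencing over the second part of larval life and at pupariation. The data covered 12 libraries, with 1 library in each of 12 groups. Whole larvae and whole eye-antennal discs were sampled at 72, 96 and 120 h after egg laying, and discs also at the white prepupal stage (WPP), when the larva has just formed its puparium. A further library at 72 h held discs still attached to the cuticular mouthparts. The eye part and the antenna part of the disc were separated and sequenced at 96 h and at 120 h. No group had a replicate, so the tested comparisons used pairs of libraries matched for tissue or age as the error term, and comparisons of 2 libraries had no replicate check and carry no p.

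Values were read as FPKM, fragments scaled to transcript length and to the mapped total, for 10893 genes. The FPKM of a library summed to between 939303 (antenna part at 120 h) and 2210255 (whole larva at 72 h), and the number of genes at 1 FPKM or more ran from 8212 (antenna part at 120 h) to 9664 (whole larva at 120 h). The number of reads per library is unknown from these values. Between 212 and 609 genes were listed at 0 in each of 11 libraries, and 981 in the WPP library. The 10 highest genes, many of them small noncoding RNAs, took 17.8% of the FPKM in the antenna part at 120 h and 52.1% in the whole larva at 72 h, and RpL41, which encodes a very short ribosomal protein, was the highest gene in 3 libraries. Across 9550 genes, which are not independent replicates, Pearson's r of log2(FPKM + 1) was 0.946 between the whole disc and the eye part at 96 h. It was 0.934 between the discs with and without mouthparts at 72 h and 0.376 between the whole larva at 72 h and the WPP disc.

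The whole-disc libraries were set against the weighted mean of their separated parts to describe how far separately made libraries of like tissue differed. The eye part received a weight of 62% at 96 h and 61% at 120 h. Examples of the genes that set the weight, which differ at least 4-fold between the parts, were gl and Dll. The gene gl, a zinc finger factor of photoreceptor precursors, stood at 68.7 FPKM in the whole disc at 96 h against 123 in the eye part and 5.17 in the antenna part. Dll, a homeobox factor of the antenna and legs, stood at 57.8 against 7.19 and 129.5. The median absolute deviation from the mean was 0.14 on the log2 scale over 7643 genes at 96 h and 0.23 over 7583 genes at 120 h. A deviation beyond 2-fold was found for 5.76% and 5.72% of these genes, and it depended on transcript length: 65.9% and 65.6% of the genes under 200 nt deviated that far, against 1.29% and 1.2% of those of at least 1000 nt. Small nucleolar RNAs and microRNA precursors led many of the ranked lists of single pairs, and for those pairs mainly genes with transcripts of at least 1000 nt were taken as examples, a choice made after the values had been seen.

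**Figure D1:**
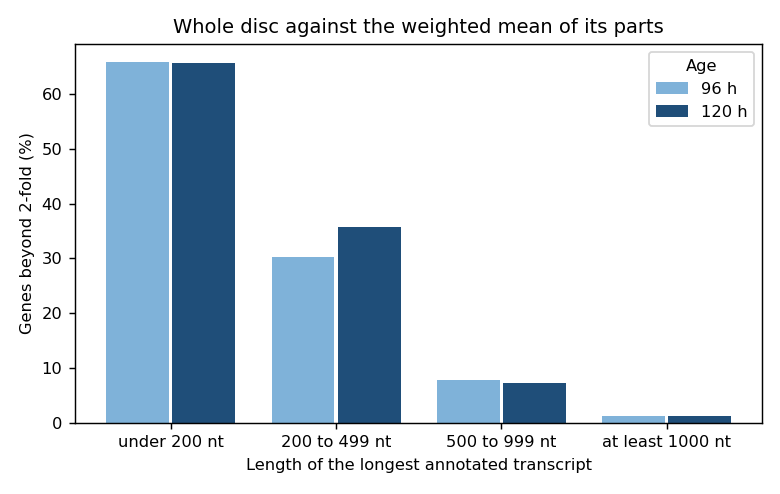
Percent of genes (vertical axis) whose level in the whole eye-antennal disc differed more than 2-fold from the weighted mean of the eye part and the antenna part, by the length of the longest annotated transcript (horizontal axis). Light bars show 96 h and dark bars 120 h, with 1 library for each tissue and age, and the bars run from 65.9% under 200 nt to 1.29% at 1000 nt or more at 96 h.

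The eye part was compared with the antenna part to find the genes that mark the 2 territories of the disc. Retinal determination genes were higher in the eye part for 6 of 12, photoreceptor and cone cell genes for 10 of 17, and antenna genes were higher in the antenna part for 7 of 13. The highest difference among named protein-coding genes was that of gl (FBgn0004618), at log2 4.36 (SE 0.18, adjusted p = 0.00395), with 123 and 126 FPKM in the eye part at 96 and 120 h against 5.17 and 5.03 in the antenna part. Dll (FBgn0000157) differed by -3.73 (SE 0.21, adjusted p = 0.00447), with 129.5 and 80.02 FPKM in the antenna part against 7.19 and 6.38 in the eye part. Of 9081 genes tested with limma, 159 were higher and 126 lower in the eye part at a Benjamini-Hochberg adjusted p under 0.05, and all 285 went the same way at both ages. This agreement is no separate support, because a difference between the ages adds to the error of the test.

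Among the 12 measured genes of retinal determination, the transcription factors and cofactors that commit cells to eye fate, 6 were higher in the eye part and none was lower (8 and 0 when adjusted over the list alone). These were eya at 3.51 (SE 0.22, adjusted p = 0.00527), so at 3.10 (SE 0.17, adjusted p = 0.00447), ey at 3.08 (SE 0.16, adjusted p = 0.00417), dac at 2.66, Optix at 2.09 and toy at 1.95, and the estimate for dan was 2.0 (SE 0.44, adjusted p = 0.137). Of 17 genes of photoreceptor and cone cell specification, 10 were higher and 1 was lower (13 and 1 when adjusted over the list alone). They included lz, a Runt-domain factor of the later-recruited cells, at 3.16 (SE 0.19, adjusted p = 0.00479), the homeobox gene ro at 3.09, the receptor tyrosine kinase gene sev at 2.98 and the orphan nuclear receptor gene svp at 2.92. The lower member was ct, a homeobox gene that also belongs to the antenna list, at -1.70 (SE 0.26, adjusted p = 0.0422). Genes of neurons followed: 5 of 18 were higher (10 when adjusted over the list alone), among them scrt at 4.01, Appl at 3.73, Ank2 at 3.52 and futsch at 2.68. Signals of the morphogenetic furrow were higher for 2 of 19 genes, aos, a secreted inhibitor of the EGF receptor, at 2.57 and pnt, its ETS-domain effector, at 1.38 (7 when adjusted over the list alone). Outside the lists, ru, which encodes a rhomboid-family protease, was higher by 4.09, and twit by 4.10.

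Several other lists had 1 or 2 members past limma, with 285 of 9081 over all genes. The Notch target E(spl)mgamma-HLH was the 1 of 11 E(spl) genes higher in the eye part over all genes, at 2.69 (SE 0.18, adjusted p = 0.00548) (4 higher and 1 lower when adjusted over the list alone). The eye-specific protein kinase C gene inaC, at 3.22, was the 1 of 12 phototransduction genes past the test (1 higher and 1 lower over the list alone). An enzyme gene of brown pigment synthesis, cn, at 3.28, was the 1 of 11 eye pigment genes (1 over the list alone). The adhesion genes rst and kirre, which act in ommatidial patterning, were higher by 2.21 and 1.91, as 2 of 8 genes of the IRRE adhesion list (3 over the list alone). The glial genes repo, at 1.99, and loco, at 1.5, were 2 of 11 (4 over the list alone), and nerfin-1, at 3.19, 1 of 7 neuroblast genes (2 over the list alone). In the cell cycle list, dap, an inhibitor of cyclin-dependent kinases, was the 1 of 27 genes that differed, at 1.16 (1 over the list alone). Hsp67Bc, a small heat shock protein gene, was the 1 of 14 stress genes, at 2.16 (1 higher and 1 lower over the list alone).

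In the antenna part, 7 of 13 genes of antenna and appendage patterning were higher and none was lower than in the eye part (11 when adjusted over the list alone). After Dll at -3.73 came the zinc finger gene disco at -3.02 (SE 0.17, adjusted p = 0.00447), the homeobox gene al at -2.63 (SE 0.33, adjusted p = 0.0332), ss, a bHLH-PAS factor of antennal identity, at -2.39 (SE 0.16, adjusted p = 0.00594), Lim1 at -2.38, ct at -1.70 and bab2 at -1.63. Outside the list, the forkhead gene fd96Cb differed by -3.56, TfAP-2 by -3.21, Sp1 by -3.12, the T-box genes mid and H15 by -3.18 and -3.14, and the odorant-binding protein gene Obp56a by -3.96. Among markers of other tissues, 6 of 13 muscle genes were lower in the eye part (9 when adjusted over the list alone), with Mlc1, a myosin light chain, at -2.99 (SE 0.32, adjusted p = 0.0173), from 1181 FPKM in the antenna part at 96 h and 120.0 in the eye part. In a list of 10 ring gland genes, of an endocrine organ near the brain and chosen after the data were seen, the values of the antenna part exceeded those of the eye part by a mean log2 of 1.57 at 96 h (range 1.12 to 2.07) and 0.68 at 120 h (range -0.04 to 1.49). Limma called 0 of the 10 (8 with an unadjusted p under 0.05), and the lowest adjusted p was that of jhamt, 0.0546. The medians of the midgut and fat body lists, of which no gene passed, lay towards the eye part, at 0.86 (percentile 99.88) and 0.29 (percentile 99.51). Of 24 cuticle genes, 2 were higher in the eye part and 1 was lower (4 and 2 over the list alone), including Lcp65Af at 2.84, Lcp65Ad at 2.51 and Pcp at -2.61.

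Limma called 0 genes over all genes in 9 lists. The number of measured members with an unadjusted p under 0.05 was 5 of 21 for ecdysone response, 0 of 17 for ribosome biogenesis, 1 of 11 for fat body, and 0 of 7 for salivary gland glue. It was 1 of 11 for hemocytes, 0 of 10 for midgut and digestion, 2 of 5 for trachea, 0 of 1 for the male germ line and 0 of 3 for male dosage compensation. Of all 9081 genes 1348 had an unadjusted p under 0.05. When adjusted over the list alone, 1 hemocyte and 1 trachea gene were higher in the eye part and 0 genes of the other 7 lists passed. The mitochondrial genome list had 1 of its 13 genes among the deposited values and none above the filter. The counts of the comparison rested on both eye libraries: without the eye part at 96 h limma called 1 gene higher and 0 lower (923 with an unadjusted p under 0.05), and without the eye part at 120 h 0 higher and 1 lower (879 unadjusted). Without the antenna part at 96 h they were 303 and 110, and without the antenna part at 120 h 175 and 195. Over the 9 alternatives that kept the eye and antenna libraries, the number of genes called ran from 6 to 13 for photoreceptor genes higher in the eye part, from 5 to 8 for retinal determination genes, from 5 to 11 for antenna genes and from 4 to 11 for muscle genes higher in the antenna part. Among the genes named here, the calls of sev, ct, Ank2, repo, al and Lcp65Ad ended with median-ratio scaling of the libraries, those of ro, Optix, pnt and dap with eBayes without trend and robust, and those of H15 and Mlc1 with a pseudocount of 5.

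**Figure D2:**
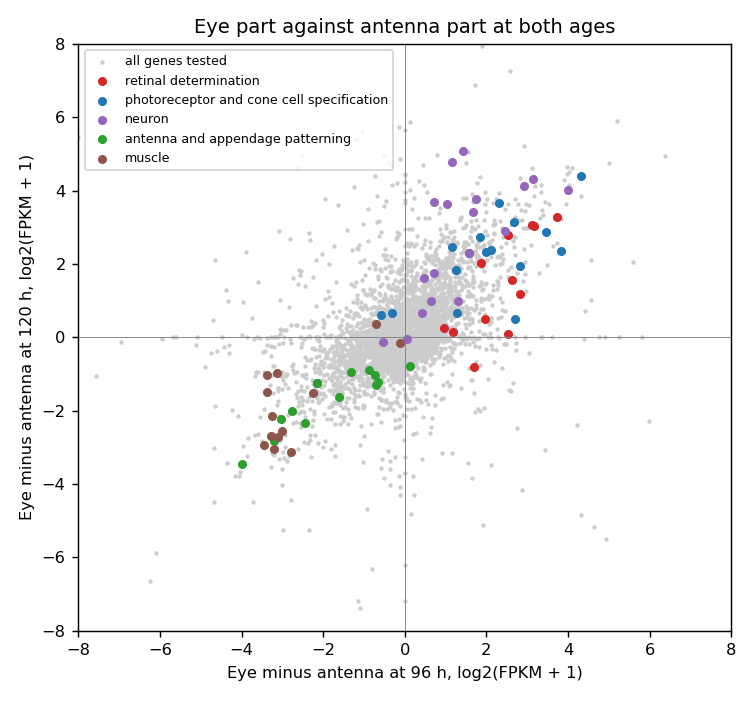
Log2 difference of FPKM + 1 between the eye part and the antenna part at 96 h (horizontal axis) and 120 h (vertical axis), with 1 point per gene, all 9081 tested genes in grey and 5 gene lists in colour. Retinal determination and photoreceptor genes lie mostly in the upper right and antenna and muscle genes in the lower left, with gl at log2 4.36 and Dll at -3.73 over both ages, and 7 genes fall outside the axes, which end at 8.

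Discs at 120 h were compared with discs at 96 h over 3 pairs of libraries, the eye part, the antenna part and the whole disc, to find what changed in late larval life before pupariation. Of 21 genes of the ecdysone list 3 rose over all genes, Hr3, Eip78C and ImpL1. Hr3 (FBgn0000448), a nuclear receptor induced by the steroid hormone ecdysone, rose by log2 4.88 (SE 0.23, adjusted p = 0.00308), from 0.276, 0.0275 and 0.528 FPKM in the eye part, antenna part and whole disc to 42.3, 36.7 and 30.6. The nuclear receptor gene Eip78C rose by 2.83 (SE 0.27, adjusted p = 0.0182) and ImpL1, an ecdysone-inducible gene of discs, by 3.12 (SE 0.42, adjusted p = 0.0489), a call that ended under 5 of 9 alternatives (highest adjusted p 0.152). Outside the list, Blimp-1, an ecdysone-inducible zinc finger repressor, rose by 4.81 (SE 0.23, adjusted p = 0.00308) and the serpin gene Spn100A by 4.79 (SE 0.21, adjusted p = 0.00265). Of 9081 genes tested with limma, 86 rose and 106 fell at a Benjamini-Hochberg adjusted p under 0.05, all 192 in the same direction in all 3 pairs, and 1655 had an unadjusted p under 0.05. The test itself favours such agreement, since its error grows when pairs differ.

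Over the ecdysone list, 3 of 21 measured genes rose and none fell over all genes, while 10 rose and 5 fell when adjusted over the list alone. The surface protein gene ImpE2 had the highest estimate of the list, 4.97 (SE 0.58, adjusted p = 0.0521), which missed the threshold, as did ImpE3 at 3.46 (SE 0.44, adjusted p = 0.0652) and ImpE1 at 3.17 (SE 0.48, adjusted p = 0.0793). Also outside the ecdysone list, Cpr72Ea, a cuticle protein gene, rose by 3.37, tnc, which encodes a mucin-like matrix protein, by 2.73, the chitinase gene Cht5 by 2.34 and Sb, a transmembrane serine protease needed for disc eversion, by 2.19. In the antenna list bab2, a BTB-domain factor of distal antennal segments, was the 1 of 13 that rose, at 1.16 (SE 0.12, adjusted p = 0.0222) (1 over the list alone), and in the stress list Hsp67Bc the 1 of 14, at 1.08 (5 over the list alone). Retinal determination and photoreceptor genes had 0 of 12 and 0 of 17 past limma over all genes (3 and 3 with an unadjusted p under 0.05), and 2 fell and 3 rose, respectively, when adjusted over the list alone. Of the E(spl) genes 0 of 11 passed over all genes (5 unadjusted) and 4 rose over the list alone. A change in the eye part alone cannot be decided by this fit, since a difference between tissues adds to its error. With 1 library per tissue and age, the retinal determination median changed by -0.62 in the eye part and 0.15 in the antenna part. For photoreceptor genes (16 measured in both) the medians were 0.62 and -0.03, and for neuronal genes (13) 0.49 and -0.08. For E(spl) genes (10) they were 0.47 and 0.69, a rise in both parts.

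In the cell cycle list 3 of 27 fell over all genes and none rose, and 14 fell when adjusted over the list alone. They were Mcm5, a subunit of the replicative helicase, at -0.99 (SE 0.13, adjusted p = 0.0375), the ribonucleotide reductase gene RnrL at -0.95 (SE 0.13, adjusted p = 0.0434) and the licensing factor gene dup at -0.94 (SE 0.14, adjusted p = 0.0478), with Mcm5 at 59.3, 55.3 and 59.4 FPKM at 96 h and 26.1, 28.0 and 32.3 at 120 h. All 3 calls ended with median-ratio scaling, with no filter on low values and with eBayes without trend and robust, and the falls in the list ran from 0 to 11 over 9 alternatives. In the furrow list hry, a bHLH repressor expressed ahead of the furrow, was the 1 of 19 that fell, at -1.33 (SE 0.14, adjusted p = 0.022) (1 over the list alone). Among markers of other tissues, 6 of 13 muscle genes fell (12 over the list alone), including Mlc1 at -4.87 (SE 0.26, adjusted p = 0.00498), Act57B at -4.01 and up, a troponin T gene, at -3.37. Of 11 fat body genes 4 fell (2 rose and 7 fell over the list alone), among them the larval serum protein genes Lsp1gamma at -3.18 (SE 0.22, adjusted p = 0.00839) and Lsp1alpha at -3.23, and Fbp2 at -2.53. Of 24 cuticle genes 1 rose and 4 fell (4 and 10 over the list alone), with Lcp65Ac at -4.75 (SE 0.19, adjusted p = 0.00265) and Lcp4 at -2.55.

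Limma called 0 genes over all genes in 13 other lists at this age step. The number of measured members with an unadjusted p under 0.05 was 1 of 12 for phototransduction, 5 of 18 for neurons, 2 of 11 for glia, 4 of 17 for ribosome biogenesis (median log2 -0.35) and 0 of 11 for eye pigment. It was 2 of 8 for IRRE adhesion, 3 of 7 for glue, 6 of 11 for hemocytes, 3 of 10 for midgut, 1 of 5 for trachea, 2 of 7 for neuroblasts, 1 of 1 for the male germ line and 0 of 3 for dosage compensation. When adjusted over the list alone, 1 glue, 1 trachea and 2 neuroblast genes rose, 1 male germ line gene fell and 0 genes of the other 9 lists passed. Without the eye part at 96 h limma called 0 genes that rose and 1 that fell (1029 with an unadjusted p under 0.05), and without the eye part at 120 h again 0 and 1 (1024 unadjusted). Without the antenna part at 96 h or at 120 h the rises numbered 144 and 148, and without the whole disc at 96 h or at 120 h the falls numbered 215 and 233. Among the other genes named here, the calls of Cpr72Ea and Hsp67Bc ended with median-ratio scaling, those of bab2, hry, Lsp1alpha and Fbp2 with eBayes without trend and robust, and that of Cht5 with a filter of 5 FPKM in 2 libraries.

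**Figure D3:**
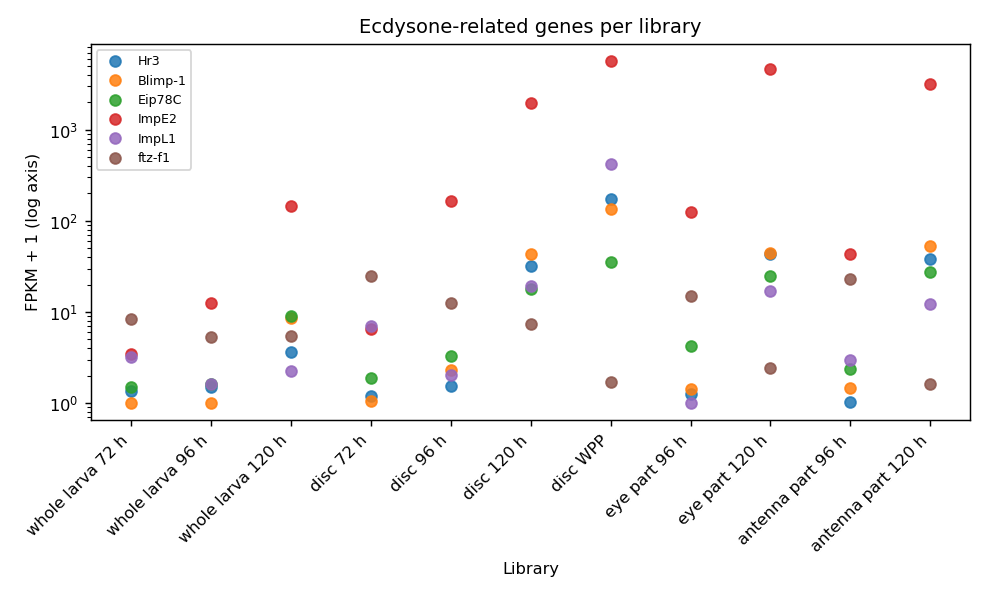
FPKM + 1 on a log axis (vertical) of 6 genes of the ecdysone hierarchy in 11 libraries (horizontal axis), with 1 point per gene and library. Hr3 stood at 0.528 FPKM in the whole disc at 96 h, 30.6 at 120 h and 174 at WPP, while ftz-f1 stood at 11.5, 6.43 and 0.719.

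Whole discs at 72 and 96 h were compared as single libraries, with a rule of size in place of a test: a gene counted as higher or lower when its log2(FPKM + 1) differed by at least 1 and the higher library held at least 5 FPKM. Photoreceptor and cone cell genes were higher at 96 h for 13 of 16. The regulator lz stood at 1.76 FPKM at 72 h and 21.1 at 96 h (log2 3.01), gl at 10.2 and 68.7 (2.63). The spalt zinc finger gene salr was higher by 2.56 and phyl, an adaptor that triggers degradation of the Tramtrack repressor, by 2.45. Of 7842 genes considered, 394 were higher and 867 lower at 96 h, or 16.1%, with a median of 0.05 over all genes, and 110 of the higher and 402 of the lower genes had no name beyond a CG or CR number.

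Of 16 photoreceptor and cone cell genes 13 were higher and none was lower, and the list's median, 1.63, lay at percentile 100 of 10000 random lists of matched expression. Notch targets of the E(spl) complex were higher for 9 of 10 (median 1.36, percentile 100), with E(spl)mdelta-HLH at 2.23. Furrow signals were higher for 5 of 19 (median 0.61, percentile 100), including rho, the protease that releases EGF receptor ligands, at 1.85, the proneural gene ato at 1.24 and sca at 1.2. Neuronal genes were higher for 8 of 17 and lower for 1 (median 1.2, percentile 100), with scrt at 3.59, Appl at 2.77 and cpx, the lower gene, at -1.67. Of the retinal determination genes 2 of 12 were higher, danr at 1.66 and dan at 1.54, with a median of 0.19 (percentile 88.0). Antenna genes were higher for 5 of 12 (median 0.94, percentile 99.99), al by 2.24, bab2 by 2.23 and ss by 1.80. The IRRE adhesion genes were higher for 3 of 8 (median 0.72), rst by 1.85 and kirre by 1.76. The pigment gene cn was higher by 2.17 as 1 of 10, inaC by 2.41 as 1 of 10 phototransduction genes and nerfin-1 by 2.04 as 1 of 5 neuroblast genes.

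Ecdysone genes moved both ways from 72 to 96 h, with 5 of 21 higher and 4 lower (median 0.52, percentile 100). ImpE2 was higher by 4.66 and ImpE3 by 2.48, and Edg78E, a pupal cuticle gene, was lower by -3.59 and Cyp18a1, an enzyme that inactivates ecdysone, by -2.98. Genes of the heat shock and stress list were higher for 5 of 14 and lower for 1 (median 0.50), led by Hsp67Ba at 4.18 and Hsp23 at 3.55. No gene of the cell cycle (27), ribosome biogenesis (17), glia (11), trachea (5), male germ line (1) or dosage compensation (3) lists passed the rule of size, with medians of 0.04 for the cell cycle and -0.34 for ribosome biogenesis. Among markers of other tissues, 20 of 32 cuticle genes were lower at 96 h and 4 higher (median -3.12), with Cpr65Av, outside the list, at 458 and 0.350 FPKM. Muscle genes were lower for 10 of 13 (median -1.79, percentile 0), midgut genes for 6 of 9 (median -2.79) and fat body genes for 4 of 12, with 2 higher. So were hemocyte genes for 2 of 10, and glue genes for 3 of 5 with 2 higher, Sgs7 by 6.48. With 1 library at each age these differences had no replicate check, and at transcripts of at least 1000 nt 249 genes were higher and 374 lower.

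**Figure D4:**
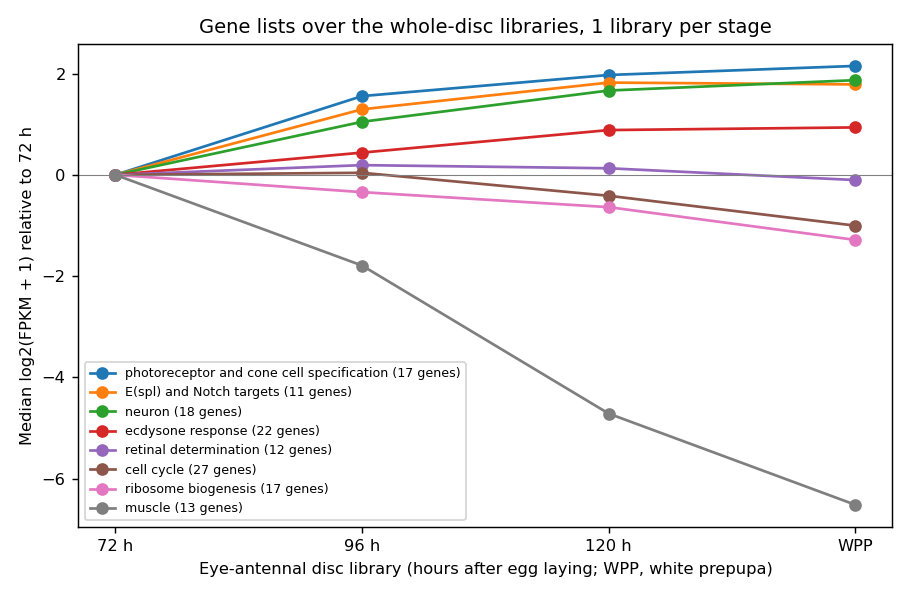
Median log2(FPKM + 1) of 8 gene lists in the whole-disc libraries (vertical axis), each relative to its value at 72 h, over 72, 96 and 120 h after egg laying and WPP (horizontal axis), with 1 library per stage. Photoreceptor genes end at 2.15, cell cycle genes at -1.0 and muscle genes at -6.52.

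Between the whole discs of 96 and 120 h, Hr3 was higher at 120 h by 4.37, Blimp-1 by 4.24 (outside the ecdysone list), ImpE2 by 3.54, from 166 to 1946 FPKM, and ImpL1 by 3.24. Of 20 ecdysone genes 7 were higher and 1 was lower (median 0.53, percentile 100). In all, 444 of 7538 genes were higher and 385 lower at 120 h, or 11.0%, with 209 and 149 at transcripts of at least 1000 nt. Among photoreceptor genes 2 were higher, sv, a Pax factor of cone cells, by 1.42 and pros, a homeobox factor of photoreceptor R7 and cone cells, by 1.41, of 17 measured (median 0.52, percentile 99.99). The synaptic gene brp was higher by 1.83 and jeb by 2.37 among 4 of 18 neuronal genes, eyg by 1.10 as 1 of 12 retinal determination genes, and 1 of 10 E(spl) genes (median 0.62). The cell cycle list had a median of -0.48, at percentile 0, with 1 of 27 genes past the rule, the ribonucleotide reductase gene RnrS at -1.08, and hry was the 1 of 19 furrow genes past it, at -1.30. Muscle genes were lower for 10 of 13 (median -2.78), Mlc1 by -4.25. Cuticle genes were lower for 10 of 24 with 3 higher, and fat body genes for 4 of 11 with 2 higher. The corpus allatum gene jhamt, which encodes an enzyme of juvenile hormone synthesis, was lower by -2.92, from 63.4 to 7.50 FPKM.

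At pupariation 8 of 21 ecdysone genes were higher than at 120 h, as were 6 of 11 fat body genes, markers of another tissue. The source of the fat body transcripts in this single library was not tested. ImpL1 was higher at WPP than at 120 h by 4.42, Cyp18a1 by 2.90 and Hr3 by 2.47, to 174 FPKM. In the ecdysone list 2 genes were lower, with a median of 0.53 (percentile 100). Outside the list, the ecdysone-induced gene Eig71Ea was higher by 6.58, and Drsl5, a drosomycin-like peptide gene, by 6.06. Proneural amos, which specifies olfactory sensilla, went from 0.0393 to 6.82 FPKM (2.91) as 1 of 14 antenna genes. The gene pros was higher by 2.01 as 1 of 17 photoreceptor genes, while KP78b, whose span overlaps it, went from 31.2 to 0.138 FPKM, and moody, a receptor of the glial blood-brain barrier, by 1.59 as 1 of 11 glial genes. Stress genes were higher for 5 of 14 and lower for 1 (median 0.50). Of 7559 genes, 381 were higher and 706 lower at WPP, or 14.4%, with a median of -0.12 over all genes and 199 and 370 at transcripts of at least 1000 nt.

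Median differences at WPP were -0.54 for the 27 cell cycle genes and -0.55 for the 17 ribosome biogenesis genes (percentiles 0 and 0.05). Only Cdk4, at -2.30, and fzy, an activator of the anaphase-promoting complex, at -1.25, passed the rule of size among them. The retinal determination gene dac was lower by -1.28 as 1 of 12, and the pigment gene cn by -3.10 as 1 of 11. Beside these groups, muscle genes were lower for 7 of 13 (median -1.79) and cuticle genes for 7 of 19, with 2 higher. So were hemocyte genes, for 4 of 10, including the prophenoloxidase gene PPO2 at -3.53. Another was He, from 17.3 to 0.405 FPKM, whose span overlaps another gene and which is 1 of the 63 genes described next. Fat body genes were higher for 6 of 11 (median 1.16, percentile 100), with Fbp1 at 4.68 and Lsp2 at 2.84. A set of 63 genes stood under 1 FPKM in the WPP library while at least 10 FPKM in each of the other 8 disc libraries, against 0 to 2 such genes for any of those 8 libraries. It included GstE13 at 112 FPKM at 120 h and 0.806 at WPP, and Ntmt at 44.3 and 0.0200.

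Over the whole span from 72 h to WPP, 952 of 8084 genes were higher and 1762 lower, or 33.6% (714 and 997 at transcripts of at least 1000 nt). ImpE2 was higher by 9.74, from 5.59 to 5650.4 FPKM, Hr3 by 7.19 and, outside the ecdysone list, Blimp-1 by 6.99. Of 12 fat body genes 4 were higher and 5 lower (median -0.74, percentile 3.32), with Fbp1, a fat body receptor for serum proteins, higher by 7.64. Of 17 photoreceptor genes 14 were higher (median 2.15), of 18 neuronal genes 12 (1.87) and of 11 E(spl) genes 9 (1.79). So were, of 14 antenna genes 7 (1.26) and of 22 ecdysone genes 11, with 3 lower. These lists lay at percentile 100, apart from the antenna list at 99.99. Cell cycle genes were lower for 14 of 27 (median -1.0), Mcm5 by -2.01, from 68.4 to 16.2 FPKM. Ribosome biogenesis genes were lower for 13 of 17 (median -1.29), nop5, a small nucleolar ribonucleoprotein gene, by -1.42 and Surf6 by -1.45. Retinal determination genes split, with 3 of 12 higher and 3 lower, Optix by -1.91 and dac by -1.59. Muscle genes were lower for 12 of 13 (median -6.52), Mlc1 from 1493 to 1.07 FPKM, and cuticle genes for 23 of 32 (median -4.24).

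Discs left on the mouthparts at 72 h were compared with discs of that age without them. The library without mouthparts was not free of transcripts of other tissues. Mlc1 stood there at 1493 FPKM against 2933 with the mouthparts, and the ring gland gene Akh at 427 against 247. Cuticle genes were higher with the mouthparts for 21 of 35 measured and lower for none (median 1.22, percentile 100). Among them were the larval cuticle genes TwdlT at 2.32 and Ccp84Ad at 2.32, and Cpr23B, outside the list, at 2.90, from 20.6 to 160.0 FPKM. Muscle genes had 3 of 13 past the rule (median 0.92, percentile 99.86), Mlc2 at 1.5 and TpnC73F at 1.38. Neuronal genes were higher for 4 of 17, cpx by 1.5, ecdysone genes for 5 of 21, ImpL1 by 1.79. Others were higher too, stress genes for 4 of 14, glue genes for 3 of 3, trachea genes for 2 of 5 and fat body genes for 2 of 11. No gene of the retinal determination, furrow, photoreceptor, E(spl), antenna, cell cycle or ribosome biogenesis lists passed the rule. The medians were -0.42 for retinal determination, -0.42 for E(spl) and -0.29 for the cell cycle (percentiles 0.02, 0.03 and 0.145). After median-ratio scaling they were -0.31, -0.30 and -0.18. Of 8026 genes, 721 were higher and 131 lower, and at transcripts of at least 1000 nt the numbers were 305 and 12.

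Whole discs were compared with whole larvae at 72, 96 and 120 h to find genes enriched in the disc. Retinal determination genes were higher in the disc for 12 of 12 and furrow genes for 17 of 19, and the larva was higher for 15 of 16 midgut, 9 of 12 fat body and 11 of 13 muscle genes. The Pax6 gene toy was higher in the disc by log2 5.35 (SE 0.47, adjusted p = 0.000332), with 164, 212 and 133 FPKM at the 3 ages against 1.84, 1.91 and 7.38 in the larva, ey, its paralogue, by 4.51 (SE 0.45, adjusted p = 0.000286), eya by 4.45 (SE 0.37, adjusted p = 4.43e-05) and ato by 4.34 (SE 0.34, adjusted p = 3.37e-05). The midgut protease gene Jon25Biii was lower by -11.76 (SE 0.40, adjusted p = 8.43e-07) and the larval cuticle gene Lcp3 by -10.54 (SE 0.44, adjusted p = 1.17e-06). Of 9993 genes tested with limma, 3588 were higher and 1416 lower in the disc (71.7% of the calls higher) at a Benjamini-Hochberg adjusted p under 0.05. Of these, 5001 of 5004 went the same way at all 3 ages, which the test favours in the same manner. The median of all genes was 0.62 on the values as deposited and -0.12 after scaling by the median ratio over expressed genes, where 1452 were higher and 1971 lower, and scaled medians are given beside several of those of the values as deposited.

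All 12 retinal determination genes were higher in the disc (12 when adjusted over the list alone, median 3.75, scaled 3.09). So were 17 of 19 furrow genes (17 over the list alone, median 2.61, scaled 1.92), with hry at 0.69 (SE 0.55, adjusted p = 0.321) and rho at 0.32 (SE 0.37, adjusted p = 0.485) the exceptions. Higher too were 10 of 11 E(spl) genes (10 over the list alone), E(spl)mgamma-HLH at 4.51, 8 of 13 antenna genes (8 over the list alone), Dll at 3.09, and 7 of 8 IRRE adhesion genes (7 over the list alone). Of 17 photoreceptor genes 12 were higher, gl at 4.36 (SE 0.43, adjusted p = 0.000197), and 1, pros, was lower at -1.21 (SE 0.43, adjusted p = 0.0426) (12 and 1 over the list alone). Proliferation and growth genes followed: 25 of 27 cell cycle genes were higher (26 over the list alone, median 2.52, scaled 1.71), among them stg, the Cdc25 phosphatase, at 3.67 (SE 0.38, adjusted p = 0.000191) and Cdk1 at 3.70 (SE 0.61, adjusted p = 0.0058), and 16 of 17 ribosome biogenesis genes (17 over the list alone, median 1.80, scaled 1.02), nop5 at 2.49. Of 8 genes of the prothoracic gland, a part of the ring gland, in the list chosen after the data were seen, 7 were higher in the disc, from spok, a steroidogenic gene, at 4.86 (SE 0.70, adjusted p = 0.00601) to tor at 1.64. The other, sro, was at 1.18 (SE 0.84, adjusted p = 0.301), with 19.9, 87.2 and 27.5 FPKM in the disc at 72, 96 and 120 h and 1.29, 43.3 and 43.3 in the larva. Nothing in the labels says whether ring gland tissue was removed from the discs.

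In the lists that follow, counts stand beside 3588 higher and 1416 lower of 9993 over all genes. Of 18 neuronal genes 5 were higher and 2 lower (4 and 2 over the list alone, median 0.65, percentile 50.55), the synaptotagmin gene Syt1 at -2.27. Of 12 glial genes 5 were higher and 1 lower (5 and 1 over the list alone, percentile 79.8), Eaat1, a glutamate transporter, at -3.19. Ecdysone genes gave 6 of 22 higher, ImpE1 at 3.14, and 4 lower, the dehydrogenase gene Ldh at -2.67 (6 and 4 over the list alone, median 0.57, percentile 34.1, scaled median -0.19). Of 11 phototransduction genes 3 were higher and 1 lower (1 and 0 over the list alone), of 12 eye pigment genes 3 and 3 (3 and 3, median 0.08, scaled -0.64), with Hn at -4.95, and of 6 trachea genes 3 and 1 (3 and 1, median 0.66, scaled -0.16). The numbers were, of 7 neuroblast genes 2 and 0 (2 and 0, median 0.32, scaled -0.12), of 14 stress genes 4 and 1 (4 and 1, median 0.15, scaled -0.65), Hsp27 at 2.86, and of 3 dosage compensation genes 1 and 0, msl-2 at 1.24. The single male germ line gene measured, mia, was higher by 1.73. In the larva, 15 of 16 midgut genes were higher than in the disc (16 over the list alone), 9 of 12 fat body genes against 1, Hsl, higher in the disc (9 and 1 over the list alone), Lsp2 at -8.56 (SE 0.53, adjusted p = 2.92e-05), 11 of 13 muscle genes (11 over the list alone), Act87E at -3.82. The larva was also higher for 6 of 11 hemocyte genes (6 over the list alone), srp at -2.90, 9 of 35 cuticle genes against 5 higher in the disc (9 and 5), and 3 of 9 glue genes (0 over the list alone).

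The disc against larva counts rested most on the 96 h libraries. Without the disc at 96 h limma called 639 genes higher and 706 lower, without the larva at 96 h 1139 and 837, and without both 982 and 830. After median-ratio scaling the genes called higher in the disc numbered 11 of the retinal determination list, 6 of the photoreceptor list, 10 of ribosome biogenesis, 2 of ecdysone response, 1 of neurons and 0 of trachea, and the calls of tor, msl-2, mia and Hsl ended. The call of pros ended with a pseudocount of 5, a filter of 5 FPKM in 2 libraries, scaling to a common total, and the disc with mouthparts in place of the disc at 72 h.

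In the whole larva from 72 to 96 h the highest rises were those of salivary gland glue and fat body genes. The glue protein gene Sgs7 went from 0.217 to 96631 FPKM (log2 16.28), Sgs8 was higher by 14.90, Fbp1 by 10.92 and Fbp2 by 7.24. Of 9 glue genes 6 were higher (median 9.75, percentile 100), of 12 fat body genes 5 higher and 1 lower, and of 17 midgut genes 6 and 2. The numbers higher and lower were, of 9 E(spl) genes 5 and 0 (median 1.45), of 20 ecdysone genes 6 and 2, and of 14 stress genes 8 and 0 (median 1.46), Hsp23 by 3.57. Cuticle genes were lower for 23 of 35 and higher for 4 (median -2.93), the Tweedle gene TwdlM by -8.82 and Lcp65Af by -8.57. Ribosome biogenesis genes were lower for 13 of 17 (median -1.14, percentile 0.02), Surf6 by -3.04 and nop5 by -2.24. Of 7415 genes 727 were higher and 1286 lower, or 27.1%, with a median of -0.14 over all genes and no replicate check (356 and 712 at transcripts of at least 1000 nt).

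From 96 to 120 h the larva as a whole showed ecdysone and stress genes higher and cuticle and muscle genes lower. Of 21 ecdysone genes 11 were higher and 2 lower (median 1.09, scaled 0.58), ImpE2 by 3.51 and Eip78C by 2.47. Of 15 stress genes 12 were higher (median 1.83, scaled 1.37), Hsp23 by 2.84. Outside the lists, Blimp-1 was higher by 3.11. Higher too were emc by 2.03 as 1 of 10 of 19 furrow genes (median 1.03, scaled 0.74) and pros by 2.02 as 1 of 6 of 14 photoreceptor genes (median 1.06, scaled 0.75). Cuticle genes were lower for 18 of 27 (median -2.04, scaled -2.64), Lcp65Ae by -8.10. Muscle genes were lower for 10 of 13 (median -1.53, scaled -2.04), Mlc1 by -2.90, and midgut genes for 7 of 17 with 3 higher, the maltase gene Mal-A3 by -3.95. Of 8171 genes 2053 were higher and 673 lower, with a median of 0.61 over all genes, and after median-ratio scaling 738 were higher and 1160 lower. Beside that shift the cell cycle list had a median of 0.60 as deposited and 0.13 after scaling, and the eye pigment list 0.12 and -0.39.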

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

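No test was run on the differences given here, which were picked because a gene list had a median below 0 in the whole disc and above 0 in the whole larva over the same ages, or the reverse, both by over 0.306 on the log2 scale (the spread of the whole disc around the mean of its parts at 120 h), with 1 library per tissue and age. From 96 to 120 h the median log2 change of the 27 cell cycle genes was -0.48 in the disc and 0.60 in the larva, and in the larva the median of all genes was 0.61. After median-ratio scaling the cell cycle medians were -0.44 and 0.13, and the larval one no longer passed the bound of 0.306. From 72 to 96 h the 12 fat body genes had a median of -0.56 in the disc and 0.35 in the larva (after scaling -0.58 over the 10 measured in the disc and 0.54 over 12 in the larva). Over the same step the midgut and digestion genes (9 with a mean of at least 1 FPKM in both tissues) had a median of -2.79 in the disc and 0.81 in the larva. The difference between disc and larva was not tested for any of the 3 lists, and no explanation was weighed.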

How the results depend on the processing

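Of the alternatives, those on transcripts of at least 1000 nt, without each single library, on genes above 0 in both libraries and without the genes near 0 at WPP alone were chosen only after the results were seen, as was the test of splits. The depth of the libraries is unknown, each fit had 2 residual degrees of freedom (1 when a library was left out), and the single pairs had no replicate, which limits every count. The splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05: the real split by age gave 192 genes and the highest other split 1, and the real split of disc and larva 5004 and the highest other 0 (1 of 10 splits as large in each case). Of the 192, 285 and 5004 genes called in the age, eye and disc contrasts, median-ratio scaling called 114, 199 and 2784 again, and eBayes without trend and robust 89, 192 and 4705. All 192, 285 and 5004 had the same direction under median-ratio scaling, as had the 192, 285 and 4993 tested under scaling to a common total. Where a count moved by over 1.5 times the cause was not tested, apart from the stricter floors and folds and, for single pairs, the longer transcripts, which take in fewer genes. The limma counts of the age and eye contrasts were higher with longer transcripts, and the cause was not tested either.

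For the age contrast, 86 genes rose and 106 fell. Median-ratio scaling gave 57 and 57, scaling to a common total 379 and 460, eBayes without trend and robust 42 and 53, and transcripts of at least 1000 nt 258 and 311. A pseudocount of 5 gave 59 falls, and the eye and antenna parts alone 239. Leaving out a library or pair, the rises ranged from 0 to 176 and the falls from 1 to 239. They were 0 and 1 in limma without the eye part pair (1038 genes with an unadjusted p under 0.05), without the eye part at 96 h (1029) and without the eye part at 120 h (1024).

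For eye against antenna, 159 were higher and 126 lower. Scaling to a common total gave 410 and 456 and moved the median of all genes from -0.02 to -0.15, transcripts of at least 1000 nt gave 331 and 245, and no filter gave 83 lower. Leaving out a library, the higher genes ranged from 0 to 303 and the lower ones from 0 to 195, with 1 and 0 without the eye part at 96 h (923 unadjusted) and 0 and 1 without the eye part at 120 h (879 unadjusted).

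For disc against larva, 3588 were higher and 1416 lower. Median-ratio scaling gave 1452 and 1971, and scaling to a common total 5215 and 1317, with medians of all genes of -0.12 and 1.13 against 0.62 as deposited. Leaving out a library or pair, the higher genes ranged from 639 to 3724 and the lower ones from 706 to 1805, the lowest without the disc at 96 h. The disc with mouthparts in place of the disc at 72 h gave 3338 and 1121.

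For the single pairs, counts are given as higher and lower. A floor of 20 FPKM gave 204 and 493 in the disc at 96 against 72 h, 260 and 246 at 120 against 96 h, 226 and 364 at WPP against 120 h, 596 and 1102 at WPP against 72 h, 461 and 84 for the mouthparts, 407 higher in the larva at 96 against 72 h and 1123 higher at 120 against 96 h. A 4-fold rule gave, in the same order, 144 and 533, 199 and 163, 167 and 384, 431 and 987, 267 and 63, 281 and 447, and 360 and 282. Transcripts of at least 1000 nt gave 249 and 374, 209 and 149, 199 and 370, 997 lower at WPP against 72 h, 305 and 12, 356 and 712, and 313 lower in the larva at 120 against 96 h. A pseudocount of 5 gave 257 higher in the disc at 96 against 72 h and 1116 higher in the larva at 120 against 96 h, where median-ratio scaling gave 738 and 1160. Counts over genes above 0 in both libraries, with a floor of 1 FPKM, and without the genes near 0 at WPP alone stayed within 1.5 times of the reported ones.

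For whole disc against the mean of its parts, the percent of genes beyond 2-fold was 5.76% at 96 h and 5.72% at 120 h. With the eye weight refitted on transcripts of at least 1000 nt it was 1.29% and 1.13%, and with a pseudocount of 0.1 it was 6.28% at 120 h. Of 229 list medians 13 changed sign under median-ratio scaling and 1 with a pseudocount of 0.1. Among those 13, 7 moved by less than the spread between libraries, and 1 had lain outside the central 95% of random lists, eye pigment in the larva at 120 against 96 h, from 0.12 to -0.39. The other 5 were in disc against larva: ecdysone from 0.57 to -0.19, eye pigment from 0.08 to -0.64, trachea from 0.66 to -0.16, neuroblast from 0.32 to -0.12 and stress from 0.15 to -0.65. For the named single genes and list medians together, median-ratio scaling left 1667 on the same side or within the spread, moved 195, ended the call of 39 and gave a call to 2. It reversed 1, the eye pigment median of the larva at 120 against 96 h. The genes of the report whose calls ended are named there.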

Other observations

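The clusters into which the authors sorted the genes, which were made from these samples and so are not independent of them, gathered several of the fixed lists. Cluster 2, of 1029 genes and highest in the eye part at 120 h, held 12 of the photoreceptor and cone cell genes, 14 of the neuronal genes and 4 of the retinal determination genes. Another 6 retinal determination genes stood in cluster 9, of 705 genes, highest in the eye part at 96 h. Cluster 5, of 616 genes and highest in the antenna part at 120 h, held 10 antenna genes. Cluster 7, of 1753 genes and highest in the disc at 72 h, held 15 cell cycle, 15 ribosome biogenesis and 12 muscle genes, cluster 3, of 948 genes and highest at WPP, held 8 ecdysone and 6 stress genes, and cluster 6, of 1606 genes and highest in the larva at 72 h, held 20 cuticle genes.

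The nuclear receptor gene ftz-f1, which is known to be repressed at high ecdysone levels, went the other way from Hr3 in these libraries. In the whole disc it stood at 23.7, 11.5, 6.43 and 0.719 FPKM at 72, 96, 120 h and WPP, and Hr3 at 0.194, 0.528, 30.6 and 174. The short ribosomal protein genes gave a separate pattern among libraries. RpL41 stood at 122508 FPKM in the disc at 72 h, 114492 at 96 h, 90129 at WPP and 187489 in the eye part at 120 h, and between 8327 and 41824 in the other 8 libraries. The median centred log2 level of the 3 ribosomal protein genes under 450 nt was 1.60, 1.5, 1.16 and 2.21 in those 4 libraries and ran from -1.69 to 0.05 in the others, while for the 75 longer ones it ran from -0.74 to 0.27 over all 12. Differences between libraries of like tissue were not limited to these short genes. The authors' cluster 10, of 867 genes, had a median centred log2 level of 0.43 in the disc at 120 h and 0.10 at 96 h. In the eye part it was -0.07 at 120 h and 0.39 at 96 h, and in the antenna part -0.06 and 0.37. Disc and parts thus went opposite ways with age in that cluster. Whether such differences enter the single pairs of whole discs was not tested, nor was any explanation of either pattern.

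Of the tests that follow, the first overlap test was set out before its result was seen, and the others (overlap among long transcripts, overlapping partners, depth, an earlier fall, and the ring gland and muscle tests) only after the values they use had been seen. The 63 genes under 1 FPKM at WPP and at least 10 FPKM in the other 8 disc libraries included 23 listed at 0, 30 of at least 1000 nt, such as GstE13, Ntmt and the noncoding RNA gene lncRNA:roX2, and 25 under 500 nt, many of them small nucleolar RNAs. Their level, a median of 42.6 FPKM in the other disc libraries, was 107% of that of all genes at 10 FPKM there. It cannot decide about a lower depth of that library. At a given FPKM the 25 genes under 500 nt hold fewer reads, and numbers of reads are unknown. Their median log2 change from 96 to 120 h in the whole disc was -0.0203. This decides nothing about an earlier fall, since genes under 10 FPKM at 120 h were left out by the choice. A different assignment of reads among overlapping genes is a candidate explanation: 83.6% of 61 genes overlapped another annotated gene against 52.3% of 4784 others, a ratio of 1.60, and among transcripts of at least 1000 nt the ratio was 1.44 (73.3% of 30 against 50.9% of 3923), too low to decide for them. The ratio of 1.60 was not matched for length: 30 of the 61 genes but 3923 of the 4784 others were of at least 1000 nt. It therefore does not decide for the shorter genes either. The 49 overlapping partners in the table had a median log2 change of 0.00117 at WPP against 120 h (quartiles -0.261 and 0.552, all genes at 10 FPKM -0.123), but for 7 genes of at least 1000 nt, such as KP78b with its partner pros, the partners would at least double by taking their reads (median log2 2.22, from FPKM times transcript length), and these changed by a median of 2.31 above that of all genes (bootstrap 95% interval 1.26 to 4.72). At least 50% of the predicted change was seen for 7 of 7, against 52 of 1066 (4.88%) among other genes. These 7 were among 15 near-0 genes of that length with a partner in the table. The rest, with smaller predictions, varied: the partner of CG11964 changed by 1.00 against 0.79 predicted, that of Rae1 by 0.13 against 0.58. For near-0 genes without a partner that would double, a fall at pupariation itself stays open and was not tested.

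Genes of the ring gland, an endocrine organ, stood above the whole larva in the whole disc at 72 and 96 h. Akh, a hormone gene of the corpora cardiaca, stood at 427 FPKM in the disc and 6.10 in the larva at 72 h. The steroidogenic gene spok stood at 521 FPKM in the antenna part and 123 in the eye part at 96 h. At 120 h sro was lower in the disc (27.5 FPKM) than in the larva (43.3), and tor was near it (3.14 and 2.28). The WPP disc held jhamt at 0.664 FPKM. Limma called 90% of 10 markers higher in the disc (not sro, adjusted p 0.301), but they were chosen after their levels were seen and 8 are of the prothoracic gland, so expression of such genes in disc cells stays open. Ring gland tissue carried along in dissection may be the source, as the 10 markers kept near one ratio between antenna and eye part at 96 h (mean log2 1.57, SD 0.288). The SD over all genes was 0.935, but it includes short transcripts, which differed most between libraries. Genes expressed together in disc cells could also keep one ratio, so the ratio does not decide the source. At 120 h the ratio was lower (mean 0.68, range -0.04 to 1.49).

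Of 13 muscle genes 6 fell with age in discs and 6 were higher in the antenna part by limma, with Mlc1 at 1181 FPKM in the antenna part and 120.0 in the eye part at 96 h. Scaling between libraries is argued against as the whole cause, since the muscle median from 96 to 120 h was -3.29 after median-ratio scaling. Muscle attached to the dissected tissue may contribute, and the test of one common ratio depended on the members used. Over all 13 genes the SD of log2 antenna to eye at 96 h was 1.07, beyond the bound of 1 set against it, a bound that overlooked 3 members with a level of their own in the discs, flr (at 82.6 and 89.7 FPKM in the eye and antenna part), sls and TpnC73F. Over the other 10, chosen after that value was seen, the SD was 0.345 (mean 3.14, range 2.24 to 3.44). Members were set apart by their WPP level relative to that of the eye part at 96 h, which also enters the ratio. Leaving out flr (0.12) and sls (0.71), which had the lowest ratios, narrows the SD by itself, so the lower SD does not decide the source. A change in muscle precursors of the disc itself was not tested and stays open.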
